A study of Mus musculus with 3 samples.

How the data were processed

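Genomic DNA of 3 mouse androgenetic haploid embryonic stem (ES) cell lines, AH129-5, Ah129-NC1 and AH129-N1, had been compared with genomic DNA from the kidney of a 129Sv male by comparative genomic hybridisation on a NimbleGen whole-genome tiling array built on mm9. Androgenetic haploid ES cells carry a single set of chromosomes of paternal origin. Per the labels, the lines were of the 129Sv background, were grown in N2B27 with 2i and LIF, and were sorted for cells in G0 or G1. Each line was hybridised on 1 array, so the series held 1 group of 3 lines and 3 arrays. The kidney DNA was common to all arrays and counted as 1 control sample, whose own spread was left out of every test against 0. The lines were named replicates 1 (AH129-5), 2 (Ah129-NC1) and 3 (AH129-N1) in the order of the records, which paired nothing.

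Each deposited table held 713358 probes, of which 664420 lay on the 19 autosomes. Per the file headers, the values were log2 brightness of the test channel (532 nm, Cy3, ES cell DNA) and the reference channel (635 nm, Cy5, kidney DNA), and log2 ratios of the channels at 3 stages, namely uncorrected, after a spatial correction, and after normalization. Per the file headers, the probe's GC content was given as a fraction. The software and version used by the authors were not given in the sources used here. The dyes in the labels and the wavelengths in the file headers gave the same direction, so a positive log2 ratio means more DNA in the ES cells than in kidney. From the values, the normalized channels of an array shared a distribution to within 0.00957 at the quantiles compared. The normalized log2 ratio was used throughout as the main value, and the series value table held the same values with a largest difference of 0, so that it is no independent alternative. Normalizing the 2 channels to a shared distribution can shrink ratios of the brightest probes, and some repeated regions had larger ratios before it. All columns of values were mapped to a sample, with 0 left over. The table names referred to segmentation output, but the tables held probe values only, and a segmentation by the authors was not used here. The design, written before the data were examined, had named that segmentation as the main and an own segmentation as its alternative, and the segments reported were computed from the probe values.

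The median log2 brightness of the test channel was 12.33, 12.45 and 12.36 in AH129-5, Ah129-NC1 and AH129-N1, and that of the reference channel 12.44, 12.475 and 12.476. The spread of neighbouring probes (noise SD) was 0.102, 0.092 and 0.100. Autosomal probe ratios correlated between arrays with Pearson's r of 0.629 to 0.773 across probes, which are not independent replicates. No 2 arrays held identical tables, with at most 3100 of all probes at equal values. The number of arrays limits the precision of every mean.

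Ratios of each array were centred on the median of its autosomal probes, which was -0.018, -0.018 and -0.019 before centring. No loess or quantile step was added. A chromosome's level was the median over its probes, given as mean ± SD over the 3 lines, and chromosome levels were tested against 0 by an exact two-sided sign-flip permutation test, whose smallest p with 3 lines is 0.25. Autosomes were to be listed where a line's median reached 0.2 in size. For regions shared by the lines, medians of 100-kb autosomal windows with at least 10 probes were tested against 0 with limma 3.58.1 (lmFit with an intercept and eBayes, R 4.3.3). A window was called at a Benjamini-Hochberg adjusted p under 0.05 and a mean of at least 0.2 in size, and adjacent called windows of the same direction were merged. Windows set a line apart where it differed from both other lines by at least 0.3 in the same direction, a comparison in which the kidney DNA cancels. Segments were found per line by penalised least squares (optimal partitioning, at least 5 probes, penalty factor 10 times the noise variance times the log of the number of probes), after probes beyond 4 noise SDs of their 10 neighbours on each side were drawn in to 2 SDs from the neighbours' median. Segments with a mean of at least 0.3 in size were called. These segmentation settings were chosen after seeing the data, and segment means are those of the smoothed values unless stated otherwise.

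Coordinates are those of the deposited tables (mm9). Chromosome lengths in the tables were the same as in the reference genome used here (NCBIM37) for 21 of 22 chromosomes. The remaining one, Y_random, pools unplaced sequence of chromosome Y. Genes were taken from the GENCODE vM1 annotation of that build (37310 genes). A gene's level was the median ratio of the probes in the gene and 25 kb on each side, with at least 5 probes, tested with limma over all autosomal genes. The probe length was not given in the sources used here. A length of 50 bp starting at the probe's position gave the GC fraction of the tables for 85.5% of 2000 probes of chromosome 19, the highest share of the lengths tried. 7 gene lists were written before the data were examined (pluripotency and germline genes, imprinted genes, cell cycle genes with tumour suppressors and oncogenes, antigen receptor loci, families known to vary in copy number, genes of chromosome X, and multicopy genes of chromosomes X and Y), and older symbols were matched through a table of synonyms.

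The named items followed a rule written before the data were examined. It took chromosomes X and Y, the autosomes with the highest and lowest mean level, the 10 highest and 10 lowest shared regions called with the same sign in all 3 lines, up to 5 regions per line with the largest difference from the nearer other line, the 3 longest gains and 3 longest losses of each line, up to 10 genes per list by size among those past the test, and up to 5 genes per region. Autosomal regions and segments outside it are said to be so in the text, apart from the short segment at -2.24 in the figure of the kappa locus. Genes outside it, chosen after their values were seen, were those given for chromosomes X and Y, those said not to have passed (Il6st, Lifr, Igf2, H19, Rb1, Atm and Igkc), and the lower genes Mkrn3, Magel2, Ndn, Ube3a and Fhit, which passed but lay beyond the 10 of their lists.

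Each procedure was tested on simulated data with noise or values taken from the real arrays. The shared-window simulation left out the rises and falls along the chromosomes that the lines shared. The segment simulation also removed them and reordered the probes. The counts of false calls therefore say nothing about calls caused by such rises and falls. Of 200 changed windows among the 23980 of the shared-window comparison, all 50 at each of the sizes 0.25, 0.4, 0.65 and 1 were recovered, with 0 false calls among 23780. Of windows lowered in Ah129-NC1 alone, on top of the real values, 0.5% were recovered at a size of 0.2, 85.5% at 0.4 and 100% at 0.65. A size of 0.2 lies under the limit of 0.3, and shifts in the other lines were not simulated. Of segments of 5 probes, 50.8% were recovered at a size of 0.65 and 100% at 1, while at 0.4 segments of 10 probes were recovered in 10% and those of 30 probes in 100%. The simulation without changes gave 0 segments over 686661 probes, and 2 of the 9 simulations with changes gave 1 false call each.

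Alternatives covered centring, the mean in place of the median, window size, probe minimum, thresholds, the prior of limma, leaving out each line, and a loess correction for the GC content of windows or gene regions. The ratio before normalization, the ratio after the spatial correction only, parts of chromosome Y, the segmentation settings, and the GC correction of gene lists and of windows that set a line apart were added after seeing the data. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 (loess), numba 0.67.0 (segmentation), matplotlib 3.10.9 and BLAST 2.17.0.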

Results

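Copy number along the genome was measured in 3 androgenetic haploid ES cell lines of the 129Sv background, AH129-5, Ah129-NC1 and AH129-N1, each on 1 array of 713358 probes against kidney DNA of a 129Sv male. Values are normalized log2 ratios of ES cells over kidney, centred on the autosomal median of each array, and n = 3 lines for every mean ± SD. The design asks whether haploid cells, after sorting in G0 or G1, kept a complete set of chromosomes, and where single lines gained or lost DNA.

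Chromosome X was higher and chromosome Y lower in all 3 lines than in the male kidney. The median ratio of the 42531 probes of chromosome X was 0.62 in AH129-5, 0.69 in Ah129-NC1 and 0.68 in AH129-N1 (mean 0.66 ± 0.034 SD, n = 3), or 1.58-fold the autosomal level relative to kidney. The kidney carried a single X per diploid set, so that a full doubling would be a log2 ratio of 1. Probes of chromosome Y, placed and unplaced together, had medians of -2.37, -2.49 and -2.59 (mean -2.48 ± 0.11, n = 3), which is 17.9% of the autosomal ratio. The 688 placed probes lay at -1.57 ± 0.079 and the 5719 unplaced probes at -2.60 ± 0.11. With 3 lines, the exact two-sided sign-flip permutation test gave p = 0.25 for each chromosome, the smallest p that 3 lines allow, and all 3 lines lay on the same side.

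Single genes of the sex chromosomes followed the same directions. All 19 measured genes of the chromosome X list lay above 0 in every line, with a median of 0.91. Xist, the RNA that coats an inactive X, had a ratio of 0.98 ± 0.052, Hprt, a purine salvage enzyme, 0.81 ± 0.021, and Dmd, the dystrophin gene, 0.60 ± 0.041, the lowest of the list. The 15 multicopy genes of chromosome X lay above 0 in all lines with a median of 0.82, from Slxl1 at 0.53 ± 0.092 to Xlr5a at 0.97 ± 0.022. All 10 genes of chromosome Y lay below 0 in every line with a median of -1.64. Sry, the testis-determining gene, was at -1.91 ± 0.21, Usp9y at -1.35 ± 0.060, and Rbmy1a1 at -2.39 ± 0.024.

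**Figure D1:**
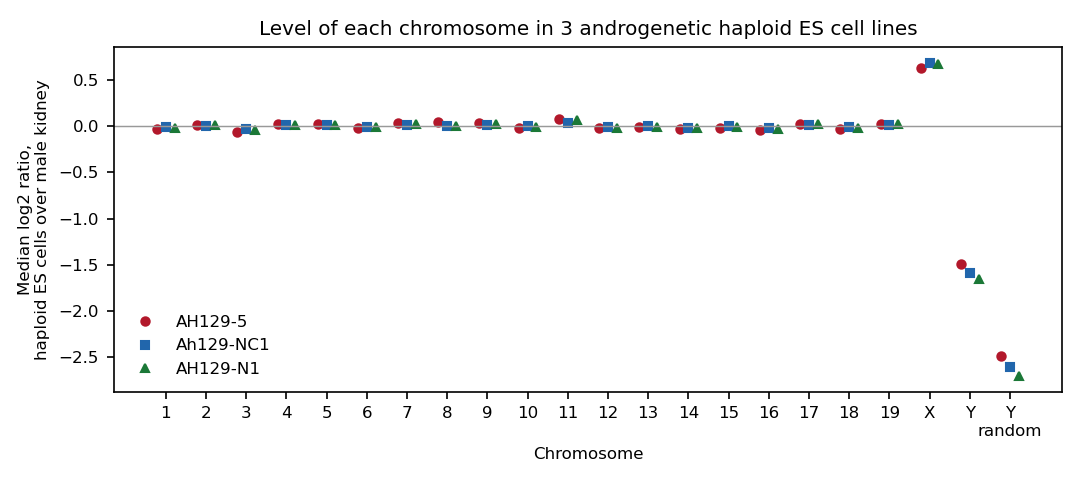
Median log2 ratio (vertical axis, ES cells over male kidney) of each chromosome (horizontal axis), with 1 point per line, red circles for AH129-5, blue squares for Ah129-NC1 and green triangles for AH129-N1. Autosomes lie near 0, X between 0.62 and 0.69, placed Y probes between -1.49 and -1.65, and unplaced Y probes between -2.49 and -2.70.

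No autosome was gained or lost as a whole at the set threshold. The listing threshold of 0.2 was reached by 0 of 19 autosomes in any line, and a threshold of 0.1 also by 0. Chromosome 11 had the highest mean level, 0.063 ± 0.023 (SD, n = 3), with 0.083 in AH129-5, 0.038 in Ah129-NC1 and 0.068 in AH129-N1. Chromosome 3 had the lowest, -0.042 ± 0.016. The exact two-sided sign-flip permutation test gave p = 0.25 for each of these, the smallest p that 3 lines allow, and a gain carried by a small share of the cells would stay below the threshold.

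AH129-5 stood apart from both other lines by 4 gained stretches, on chromosomes 4, 6, 10 and 17. The largest, at chromosome 4 from 10,700,001 to 12,500,000, covered 18 windows and 502 probes, with a mean level of 0.85 in AH129-5 against 0.056 in Ah129-NC1 and 0.068 in AH129-N1. It held 20 coding gene entries, all of them whole, among them Ccne2 (cyclin E2), Trp53inp1 (a p53-induced stress protein), Rad54b (a recombination helicase), Esrp1 (an epithelial splicing regulator) and Tmem67 (a protein of the ciliary transition zone). At chromosome 6 from 39,100,001 to 39,600,000, 5 windows averaged 1.01 in AH129-5, 0.14 in Ah129-NC1 and 0.21 in AH129-N1. That stretch held Mkrn1, Slc37a3, Dennd2a and Adck2 whole, and part of Braf, the serine/threonine kinase of the MAP kinase pathway.

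At chromosome 10 from 19,900,001 to 20,200,000, 3 windows averaged 0.72 in AH129-5 against 0.070 and 0.10 in the other lines. Bclaf1 and Fam54a lay whole within these windows, with parts of Mtap7, which binds microtubules, and of the phosphodiesterase gene Pde7b. A single window at chromosome 17 from 43,000,001 to 43,100,000, over part of Cd2ap, an adaptor of the actin cytoskeleton, was at 0.99 in AH129-5 against 0.13 and 0.21. AH129-N1 was set apart by lower levels in 2 windows of chromosome 6 from 70,100,001 to 70,300,000, at -1.08 against -0.043 in AH129-5 and 0.0055 in Ah129-NC1. These windows held 8 variable genes of the kappa immunoglobulin light chain, among them Igkv8-27, Igkv6-25 and Igkv8-21, and no coding gene of another kind.

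Of the 23980 windows compared, 27 set AH129-5 apart, all higher, 2 set AH129-N1 apart, both lower, and 0 set Ah129-NC1 apart. The mean distance of AH129-5 from the nearer other line was 0.77 at chromosome 4, 0.80 at chromosome 6, 0.62 at chromosome 10 and 0.77 at chromosome 17. In AH129-N1 the distance was -1.04. There was 1 array per line, so these differences have no replicate check and no p. The simulated windows changed by 0.2 in a single line were recovered in 0.5%, so smaller differences between the lines stayed out of reach.

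**Figure D2:**
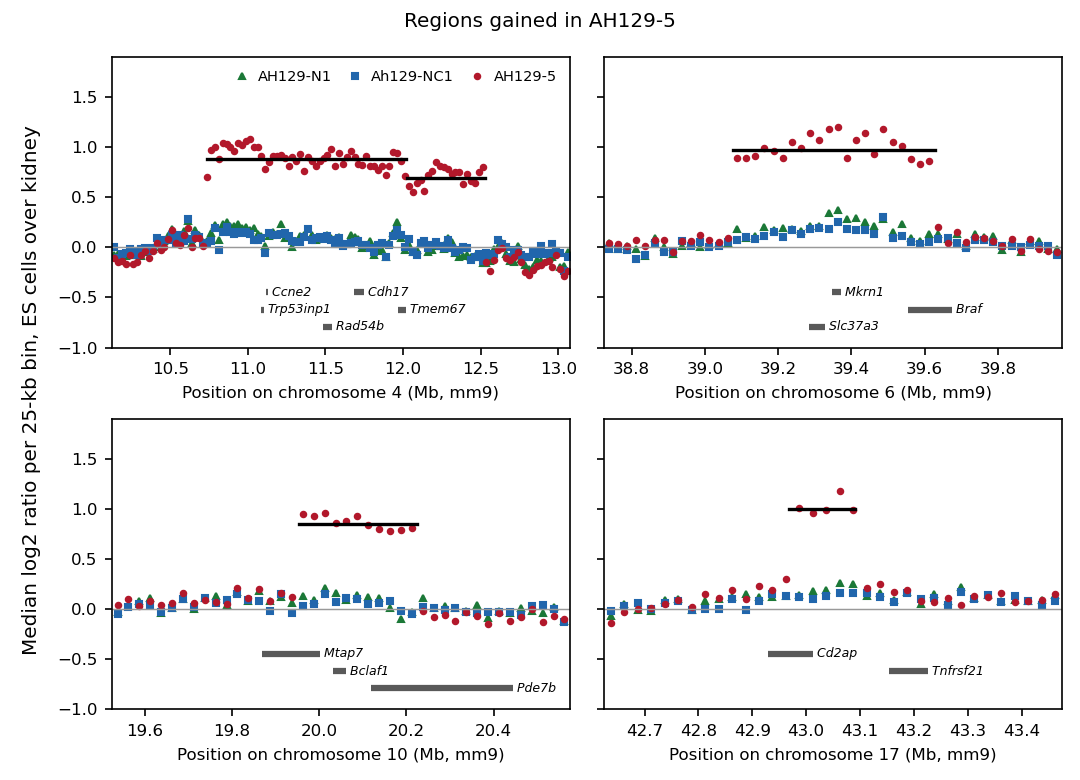
Median log2 ratio per 25-kb bin (vertical axis) against position in Mb (horizontal axis, mm9) over the 4 stretches gained in AH129-5, with red circles for AH129-5, blue squares for Ah129-NC1 and green triangles for AH129-N1. Black lines mark the means of the AH129-5 segments, which lie between 0.69 and 1.00, and grey bars mark genes.

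Segmentation of each line placed the ends of these gains and added shorter ones. In AH129-5 the gain of chromosome 4 began at 10,734,684 and ran for 1287 kb to 12,021,734 with a mean of 0.89 over 364 probes, 1.85-fold the kidney level. It went on to 12,529,109 at 0.69 over 138 probes, past Rbm12b and Fam92a; this second part was chosen after its values were seen. The gain of chromosome 6 ran from 39,076,106 to 39,628,909 (553 kb, 158 probes) at 0.98, or 1.97-fold, and took in Jhdm1d, a histone demethylase, whole. Another long gain, at chromosome 8 from 72,316,216 to 73,529,549, was lower, at 0.34, over a gene-dense stretch with 61 coding genes such as Upf1, Jund and Gdf15. The other lines were also above 0 there, at 0.12 in Ah129-NC1 and 0.22 in AH129-N1.

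Of the segments called lower in all 3 lines, 2 lay in introns of Cntnap5a and Nlgn1. A segment at chromosome 1 from 117,826,831 to 117,923,865 (97.0 kb, 29 probes) inside an intron of Cntnap5a, a neurexin family gene, had means of -1.06 in AH129-5, -0.94 in Ah129-NC1 and -1.01 in AH129-N1, which are 47.9%, 52.0% and 49.6% of the kidney level. A segment at chromosome 3 from 25,419,265 to 25,452,686 (33.4 kb, 10 probes) inside an intron of Nlgn1, a synaptic adhesion gene, had unsmoothed means of -1.35, -1.36 and -1.51. A further one, outside the rule for named items, of 5 probes at chromosome 1 from 173,413,043 to 173,425,936 near F11r, with no annotated gene, had means of -0.46, -0.64 and -0.57 but medians of 0.098 in AH129-5, 0.064 in AH129-N1 and, over a segment shifted by some kb, 0.006 in Ah129-NC1. All arrays shared the kidney DNA, so a difference common to the 3 lines, lower or higher, can lie in the cells or in the kidney. AH129-5 also had a loss at chromosome 5 from 10,875,940 to 11,932,187 over 1056 kb, at -0.30, across 13 coding entries, most of them predicted Gm genes, with Speer1-ps1 among them. The other lines were at -0.16 and -0.27 there.

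Of the gains, only that at the start of chromosome 9 was called in all 3 lines. It ran from 3,000,031 to 3,076,122, over 12 predicted genes such as Gm10722 and Gm11168. The unsmoothed means were 0.34 in AH129-5 (0.40 after smoothing), 0.45 in Ah129-NC1 and 0.44 in AH129-N1. Before normalization this gain was at 0.28 in Ah129-NC1, below the limit for a call, and at 0.31 in AH129-N1. At chromosome 7 from 26,797,856 to 26,972,319, over Cyp2b13 and part of Cyp2b9, which encode cytochromes P450, a gain was called in AH129-N1 and, over nearly the same stretch, in Ah129-NC1, but not in AH129-5. AH129-N1 was at 0.33, and the same probes averaged 0.35 in AH129-5 and 0.31 in Ah129-NC1. Before normalization the ratio there was 0.93 in AH129-N1, and that of a nearly equal segment in Ah129-NC1 was 0.86 against 0.32 after it. A stretch with no annotated gene at chromosome 8 from 15,426,531 to 15,481,545, between Myom2 and Csmd1, was called in AH129-5 (0.34) and Ah129-NC1 (0.32) but not in AH129-N1 (0.28), and in Ah129-NC1 it was 0.99 before normalization.

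Further segments were seen in single lines. AH129-N1 was lower over 160 kb of the kappa locus at chromosome 6 from 70,116,932 to 70,277,006 (mean -1.11, 41 probes). It was also lower over the adjoining 95.1 kb to 70,373,534, at -0.45, which holds Igkv6-20, Igkv6-17 and Igkv6-15. The level differed between these parts, and whether every cell lacked this DNA was not tested. AH129-N1 also gained 24.3 kb within Etv5, a transcription factor gene, at chromosome 16 from 22,401,619 to 22,425,933, at 0.61 over 8 probes, where the others were at 0.17 and 0.14. Ah129-NC1 lost 31.7 kb at chromosome 12 from 96,146,363 to 96,178,064, at -1.96 over 10 probes, with no annotated gene and Flrt2 752 kb downstream, where the others were at -0.26 and -0.19. Outside the rule for named items, AH129-5 lost 9 probes at chromosome 12 from 35,569,232 to 35,595,460, at an unsmoothed mean of -1.78 against -0.054 and -0.071 in the others, with no coding gene.

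In all, 16 autosomal segments were called in AH129-5 (11 gains, 5 losses), 9 in Ah129-NC1 (5 gains, 4 losses) and 9 in AH129-N1 (3 gains, 6 losses). Gained segments summed to 4326, 332 and 275 kb, and lost segments to 1226, 176 and 417 kb. In AH129-5, 1213 kb of the gained sum was the chromosome 8 stretch at 0.34. The chromosome 5 stretch at -0.30 made up 1056 kb of its lost sum. In both stretches the other lines lay on the same side of 0 without reaching the limit, so the sums overstate the difference between the lines. There was no test within a line, and with a threshold of 0.2 in place of 0.3 the counts were 172, 15 and 45. The SD of autosomal window levels also differed, at 0.154 in AH129-5, 0.082 in Ah129-NC1 and 0.122 in AH129-N1. A fixed threshold is therefore reached more readily in AH129-5. The counts alone do not rank the lines by their copy changes.

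**Figure D3:**
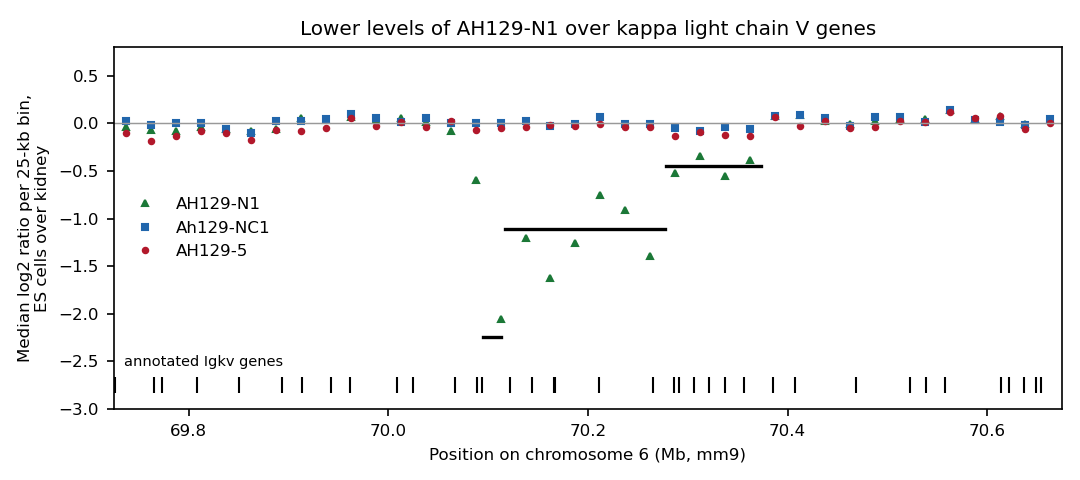
Median log2 ratio per 25-kb bin (vertical axis) against position on chromosome 6 in Mb (horizontal axis, mm9) across kappa light chain variable genes, which are drawn as vertical ticks. Green triangles (AH129-N1) fall below blue squares (Ah129-NC1) and red circles (AH129-5) over the segments drawn as black lines, with means of -2.24, -1.11 and -0.45.

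Windows that departed from the kidney level in the 3 lines together were many and mostly small. limma called 830 windows higher and 685 lower of 23980, all with the same sign in the 3 lines, in 463 higher and 380 lower merged regions. The highest region by mean was the Braf stretch of chromosome 6 (0.45 ± 0.48, adjusted p up to 0.0226), and the Cd2ap window of chromosome 17 came next (0.45 ± 0.47). 5 of the 10 highest regions, those of Braf, Cd2ap and Bclaf1 and both of chromosome 4 (0.38 ± 0.46 with Ccne2, and 0.37 ± 0.46 with Tmem67), owed their means to AH129-5, and lay between 0.087 and 0.18 without it. The others were above 0 in every line. They were chromosome 9 from 3,000,001 to 3,100,000 (0.40 ± 0.055) and chromosome 2 from 177,500,001 to 177,600,000 with Gm14322 and Gm14325 (0.33 ± 0.023), followed by the last window of chromosome 5, beyond Rfc3 (0.30 ± 0.036). A window of chromosome 11 between Alkbh5 and Llgl1 was at 0.29 ± 0.16. It also leaned on AH129-5, at 0.48 against 0.18 in Ah129-NC1 and 0.22 in AH129-N1. A window of chromosome 19 between Trpm3 and Klf9 was at 0.28 ± 0.053.

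The lowest region was the Cntnap5a stretch of chromosome 1 from 117,800,001 to 118,000,000, at -0.59 ± 0.069, with limma's adjusted p up to 0.000268. The other 9 lay between -0.26 and -0.25, and were lower in all 3 lines. They included stretches within Pcdh9, a protocadherin, on chromosome 14 (-0.25 ± 0.066), Cntnap2 on chromosome 6 (-0.25 ± 0.055), Mdga2 on chromosome 12 (-0.25 ± 0.064) and Col11a1, a collagen gene, on chromosome 3 (-0.25 ± 0.063). The remaining ones were the Gm gene cluster of chromosome 5 from 10,800,001 to 11,900,000 (-0.25 ± 0.074) and gene deserts of chromosomes 11 (-0.26 ± 0.056), 14, 16 and 18.

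These calls moved with base composition. Called windows had a median GC content of 47.6% where higher and 37.0% where lower, against 41.4% over all windows, and after a correction for GC content 180 higher and 76 lower windows were called. The lowest regions other than Cntnap5a then lay between -0.060 and -0.14, while Cntnap5a was at -0.52 ± 0.036 and chromosome 9 at 0.38 ± 0.059. In the ratio before normalization chromosome 9 was at 0.20 and the Gm14322 window of chromosome 2 at 0.57. Without centring, 430 windows were higher and 1290 lower. The counts also moved with the lines used, to 316 higher and 224 lower without AH129-5 and to 1788 and 1649 without Ah129-NC1.

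Genes of the pluripotency list lay in DNA with higher ratios. Of 28 measured members, 26 were higher in limma's test (26 when adjusted over the list alone), 0 were lower and 2 did not pass, with a median of 0.20. Nanog was at 0.27 ± 0.016 (adjusted p = 0.00094) and Pou5f1, which encodes Oct4, at 0.24 ± 0.070, both core factors of the ES cell network. Gdf3, Klf2 and Tcfcp2l1 were at 0.25 ± 0.052, 0.25 ± 0.11 and 0.24 ± 0.048, and Tet1, a 5-methylcytosine oxidase, at 0.23 ± 0.054. Il6st and Lifr, the subunits of the leukaemia inhibitory factor receptor, did not pass, at 0.041 ± 0.048 and 0.050 ± 0.018. Over all 34592 autosomal genes the median was 0.087, and 71.4% passed the test, 19898 genes higher and 4798 lower. These values are the background for the counts of every list before the GC correction. After the GC correction 19 members were higher and 3 lower, with a median of 0.072. No background over all genes is given for counts after the correction, here or for the other lists.

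Imprinted genes are expressed from a single parental copy. Of 40 measured, 23 were higher, 5 were lower and 12 did not pass (28 past when adjusted over the list alone), with a median of 0.088. Gpr1 was highest at 0.25 ± 0.046, followed by Dlk1 at 0.20 ± 0.070. The lower ones were Dcn, a proteoglycan gene, at -0.15 ± 0.041, and 4 neighbours of the Prader-Willi and Angelman region of chromosome 7, Mkrn3 (-0.12 ± 0.0075), Magel2 (-0.11 ± 0.017), Ndn (-0.10 ± 0.031) and Ube3a (-0.090 ± 0.031). Igf2 and H19 did not pass, at -0.0027 ± 0.053 and 0.030 ± 0.069. After the GC correction 10 members were higher and 13 lower.

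Cell cycle genes, tumour suppressors and oncogenes were mostly slightly higher, and Braf was higher through AH129-5. Of 32 measured, 24 were higher, 1 was lower and 7 did not pass (25 past when adjusted over the list alone). Most autosomal genes were also higher, 19898 of 34592. Braf was at 0.77 in AH129-5, 0.073 in Ah129-NC1 and 0.12 in AH129-N1 (mean 0.32 ± 0.39, limma's adjusted p = 0.0319). Cdk4, a cyclin D-dependent kinase, was at 0.25 ± 0.083, Cdkn1a, which encodes the p21 inhibitor, at 0.23 ± 0.10 and Trp53 at 0.18 ± 0.10. Fhit, at a fragile site, was the lower one, at -0.080 ± 0.018. Rb1 and Atm did not pass, at -0.026 ± 0.031 and 0.052 ± 0.018. After the GC correction 14 were higher and 7 lower.

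Of 8 measured antigen receptor genes, 3 were higher, 2 were lower and 3 did not pass (5 past when adjusted over the list alone). The constant genes of the T cell receptor beta chain were the lower ones, Trbc2 at -0.18 ± 0.041 and Trbc1 at -0.12 ± 0.0091, and Iglc3, a lambda light chain constant gene, was the highest at 0.14 ± 0.026. Igkc, the kappa constant gene, did not pass, at 0.059 ± 0.023. After the GC correction 2 were higher and 3 lower.

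In families known to vary in copy number between mouse strains, 28 of 61 measured genes were higher, 13 lower and 20 did not pass (41 past when adjusted over the list alone). Passing was no mark of this list, since over all 34592 autosomal genes 71.4% passed, 19898 higher and 4798 lower. The natural killer cell receptor genes Klra1 (-0.20 ± 0.047), Klra4 (-0.20 ± 0.071) and Klra7 (-0.16 ± 0.063) were lower. Sfi1, a centrosome gene, was highest at 0.24 ± 0.061, and Glo1, the glyoxalase gene, was at 0.23 ± 0.038. No measured gene of this list reached 0.3 in size. After the GC correction 22 were higher and 19 lower. Across the lists, 125 genes passed, and 22 of these had a mean of at least 0.2 in size.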

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

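The ratios before normalization or after the spatial step alone, the parts of chromosome Y, the segmentation settings, the GC correction of gene lists and of windows that set a line apart, and the size limit on gene calls were chosen after seeing the data. Chromosomes X and Y kept their direction under every alternative run. Without each line in turn, X lay between 0.65 and 0.68 and Y between -2.54 and -2.43, and 0 autosomes reached the threshold in any setting. No named region or segment changed sign under the alternatives run on it, and single list genes were not followed. The value table held the same values and moved nothing. The authors' segmentation, planned as the main, gave no value because the files held probe values only. No paired analysis was possible because there was 1 group.

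Shared windows, 830 higher and 685 lower as reported, came to 430 and 1290 without centring, 180 and 76 after GC correction, 23 and 2 at a mean of 0.3, and 8380 and 8524 with no limit on the mean. With 500-kb windows, of which fewer exist, they came to 85 and 78. Leaving out a line gave 316 to 1788 higher and 224 to 1649 lower, the lowest without AH129-5 and the highest without Ah129-NC1.

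Segments in AH129-5, Ah129-NC1 and AH129-N1, 16, 9 and 9 as reported, came to 172, 15 and 45 at a mean of 0.2, and to 10, 5 and 6 at 0.5. They came to 39, 18 and 25 at penalty factor 4, 31, 26 and 29 without outlier smoothing, 60, 47 and 48 before normalization, and 74, 59 and 71 after the spatial step alone. By the segment median, Ah129-NC1 had 5.

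Windows that set a line apart came to 5 in AH129-5 and 1 in AH129-N1 with 500-kb windows, and to 1 in Ah129-NC1 with window means. List genes past the test, 125 as reported, came to 76 over the gene alone, 22 with a size limit of 0.2, and 69 to 143 without each line, the lowest without AH129-N1. Apart from the limits, window size and number of lines, the cause was not tested.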

Other observations

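The tests on the count of windows in the uncorrected ratio, on GC-matched gene lists and on the mean level of the low stretches were chosen after the result was seen, and the regions of chromosome X were picked from the values themselves. Chromosome X, which the segment counts leave out, carried changes in single lines. Ah129-NC1 had lost the distal end of chromosome X from 166,498,497 to the last probe at 166,648,536 (150 kb, 29 probes), with a median of -2.74 against 0.44 in AH129-5 and 0.41 in AH129-N1. Of these probes, 21 lay below -2 in Ah129-NC1. Mid1, the coding gene before it, ends 54.8 kb upstream. Over the 14 probes just before this distal end, medians were 0.95 in AH129-5, 0.73 in Ah129-NC1 and 0.94 in AH129-N1. The 2 lines that kept the end were thus also lower over it than just before it. AH129-5 had a gain at chromosome X from 159,279,376 to 159,536,688 (257 kb, 73 probes), with a median of 1.64 against 0.86 in Ah129-NC1 and 0.94 in AH129-N1, over the whole of Syap1, Ctps2, a CTP synthase, and S100g, a calcium-binding protein gene. As a segment mean relative to the X median of each line, this gain was at 0.96, against 0.16 and 0.25. By the same measure, longer and lower X gains were called in AH129-5 from 7,096,706 to 7,916,678 (820 kb, 0.40), from 70,140,562 to 71,726,894 (1586 kb, 0.34) and from 98,274,107 to 99,462,991 (1189 kb, 0.34), and in AH129-N1 from 7,166,427 to 7,877,873 (711 kb, 0.35). Over the AH129-5 segments the other lines were also above their X median, at 0.22 and 0.32, 0.17 and 0.27, and 0.19 and 0.28 in Ah129-NC1 and AH129-N1.

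The 5 gained segments of AH129-5 above 0.6 on the autosomes had means of 0.69 to 1.00 over 2738 kb. The X level in the same array was 0.62, so choosing segments above 0.6 nearly fixed that they lay above it. The other autosomal gains of AH129-5 lay below the X level, between 0.33 and 0.54. The X level itself differed with base composition. It was 0.57 ± 0.048 in the 392 X windows lowest in GC (median 36.8%) and 0.83 ± 0.018 in the 392 highest in GC (median 41.7%) (n = 3 lines).

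Chromosome 8 was slightly higher in AH129-5 (0.045) than in Ah129-NC1 (-0.001) and AH129-N1 (0.003). A wave of another size in this array was argued against. After the part shared with the other lines was removed, chromosome 8 kept a median residual of 0.049, while the other 18 autosomes lay between -0.010 and 0.006. The authors' normalization was also argued against, since the residual was 0.051 in the uncorrected ratio, and so were a few gained stretches, since 100% of 27 blocks of 5 Mb had a residual above 0. No biological explanation was tested by the design; a hypothesis left open is an extra chromosome 8 in part of the cells of AH129-5, which a count of chromosomes in single cells would test and which was not tested here.

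The levels of 100-kb autosomal windows rose and fell together, with r of 0.90 to 0.95 between arrays across windows, which are not independent replicates. GC content of the windows as the whole cause was argued against, since the lowest r after the GC correction was 0.855, although the correction removed most calls. The correction used the GC content of the 100-kb windows only, so GC content at other scales was not tested. The authors' normalization was argued against by 1724 called windows in the uncorrected ratio against 1515. Cells in S phase left in the sort, and the kidney DNA that all arrays share and that alone would make them correlate, stay open as explanations. Early replicating genes would then be higher, and the median of the pluripotency list after GC correction, 0.072, lay at percentile 100 of 10000 lists of genes matched on probe GC, whose typical median was 0.0035. This is consistent with S phase DNA but does not tell it from other features of such genes, replication timing was not analysed here, and the cell cycle list was also high, at percentile 97.4, while the imprinted list lay at 5.93, the families variable in copy number at 48.5 and the antigen receptor list at 96.3 with 2 coding members measured. Without the GC correction the percentiles in the same order were 100, 71.7, 48.5, 59.0 and 83.8, so the place of the cell cycle and imprinted lists depended on the correction. Matched genes were drawn singly, whereas the measured stretches of Gdf3 and Dppa3, and of Dppa2 and Dppa4, overlap. The percentile of the pluripotency list can therefore overstate its distance from the matched lists.

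On chromosome X between 120,115,827 and 122,712,817, a span of 20 coding genes of which 18 are predicted Gm genes, low stretches were found in all 3 lines. Their 200 shared probes averaged -0.45 ± 0.037 (n = 3), against 0.66 ± 0.021 over the other probes of chromosome X. Absence of the sequence from the cells stays open, since that mean of -0.45 is the low level that raised the question and covers probes that match other sequence. Sequence shared with chromosome Y or unplaced contigs, which the kidney would carry and the cells would lack, is a candidate explanation. Of these probes, 56% matched chromosome Y or an unplaced contig over at least 45 bp at 90% identity, against 3.61% of the other X probes, and the matched ones were lower (-0.62 ± 0.052) than the unmatched ones (-0.25 ± 0.019). Matched probes were also lower on the rest of chromosome X (0.42 ± 0.030 against 0.67 ± 0.021), so the lower level of matched probes is not particular to these stretches. The 88 unmatched probes of the low stretches, at -0.25, also lay below the unmatched probes elsewhere on chromosome X, at 0.67. Matches to the sequence searched therefore do not account for the low level of these unmatched probes. Only 1.5% of the probes in the low stretches matched chromosome Y itself. Y_random, which holds 5719 of the Y probes, was not in the reference genome and was not searched under that name. Whether the contigs belong to chromosome Y therefore stays open, and no biological explanation was tested.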
